A study of Homo sapiens with 6 samples.

How the data were processed

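Gene expression was measured with 1-colour oligonucleotide arrays in 6 cultures of the gastrointestinal stromal tumour cell line GIST-T1 and lines derived from it. T1 is the untreated parent, with 1 array. T117 had been kept in imatinib for 7 weeks, with 1 array. R8, RA2, R9 and R2 are fully resistant lines that were selected separately, with 1 array each, after 20, 45, 52 and 60 weeks. The 4 resistant arrays were treated as independent replicates of one group, and every other group is a lone array. The biological unit is a cell line, so the number of arrays limits the precision.

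Per the file headers, the authors scanned the arrays and extracted spot intensity with Agilent Feature Extraction 10.10.1.1 on grid design 039494, annotated on GRCh37. The deposited processed signal is a background-subtracted and detrended intensity for 1 colour, on a linear scale, and it is not scaled between arrays. The deposited series table holds the same intensity multiplied by 1 constant per array, from 2.11 in R8 to 4.44 in R9. The rule that set these constants is not stated, and the column medians of that table still differed, from 121 to 149. Each array has 58717 spots other than controls and 4259 control spots. The 75th percentile of the processed signal ran from 238 in R9 to 532 in R8. Between 52.4% and 60.5% of probes were well above background. The standard deviation between spots of the same probe was 0.066 to 0.078 on the log2 scale, and no spot was saturated. T1 and T117 lie on slide 1 and the 4 resistant lines on slide 2. Slide and group can therefore not be told apart for any comparison of resistant lines with T1 or T117, while T117 against T1 and the comparisons between resistant lines stay within a slide.

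Control spots and spots that Feature Extraction marked as non-uniform or as population outliers (355 to 408 per array) were left out, and the spots of one probe were averaged. The log2 processed signal had each array's 75th percentile subtracted. Probe accessions were paired with gene symbols in a RefSeq table for GRCh38.p14, which was used for names and for the order of neighbouring genes alone. Of 50599 probes, 28174 received a symbol, standing for 20503 genes. Each gene was represented by its probe with the highest mean signal. The 17071 genes well above background on at least 1 array were tested. A single ratio with a dim side, also in the fold counts, used the lowest signal well above background on that array, or the probe's own signal where higher. It is given as a bound. The limma fits, list tests and list medians used the dim signal itself.

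The 3 groups were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings). There were 3 residual degrees of freedom, all from the 4 resistant lines, and 2.63 prior degrees of freedom. All tests were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. A p-value against a lone array assumes that this array would vary as the resistant lines do. Comparisons of 1 array with 1 array have no test and are given as ratios, with counts of genes at least 2-fold apart. Genes at least 2-fold the same way in all 8 ratios, that is 4 resistant lines against T1 and against T117, were counted. A gene was called set apart in a resistant line when it was at least 4-fold above or below each of the other 3. No paired analysis was possible because T1 and T117 have 1 array each, so the resistant lines have no partners one to one.

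For 35 gene lists fixed before the data were examined, camera was run with the preset correlation of 0.01 between genes, again with an estimated correlation, and fry beside it. With an estimated correlation camera rests on the 3 residual degrees of freedom alone, which left it little power over 35 lists. For each array, the median log2 ratio of a list to T1 was set against 10000 random lists of the same size matched on expression, as a percentile. Genes of the random lists were drawn singly, so a list whose genes vary together reaches an extreme percentile more easily. The percentile describes the array and is no test. The contrast of the resistant lines with T117 by camera was added after the data were seen.

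Genes are named by a rule fixed before the data were examined. KIT and PDGFRA come first. For each resistant contrast these are the 10 largest rises and falls past the threshold, or, if too few pass, the next by mean log2 ratio among genes at least 2-fold the same way in all 4 lines. Up to 5 bounds per direction follow. T117 against T1 has its 10 largest differences and 5 bounds per direction, each resistant line the 5 highest and 5 lowest genes set apart, and the 8-ratio genes the 10 largest per direction by their smallest ratio. List members at least 4-fold from T1, and up to 4 others per list, may be named. Probes without a gene symbol were left out of these rankings.

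The procedure was tested on simulated data with the spread of the real fit, in 10 simulations with 200 genes changed in each. limma called 0% of genes changed 2-fold, 0.2% of those changed 4-fold, 19% of those changed 8-fold and 95.4% of those changed 64-fold, and it called 2.6 unchanged genes on average. The 8-ratio rule found 71.6% of genes changed 4-fold, together with 26.3 unchanged genes on average. Detection rates for limma and the 8-ratio rule were not obtained separately for dim genes. They need not hold for genes that are dim on some arrays. camera with the preset correlation called 100% of lists shifted 2-fold and 0.1 unshifted lists on average, in data simulated without correlation between genes.

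The alternatives were normexp background correction with an offset of 50, quantile normalization, median centring, the authors' series table, no filter on dim probes, a filter on all 6 arrays, the mean over a gene's probes, limma with trend and robust settings, T1 and T117 as one group, leaving out each resistant line in turn, another set test and another fold threshold. The normexp correction was first planned on mean pixel intensity. The deposited raw intensity columns read here hold median pixel intensity of spot and local background, so that was used instead, a choice made after the files were opened. A block for the slide could not be fitted, since each slide holds other groups. Figures were drawn with matplotlib 3.10.9.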

Results

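Expression of 17071 genes was measured in the imatinib-sensitive parent GIST-T1 (T1, 1 array), in T117, a derivative after 7 weeks in imatinib (1 array), and in 4 lines that grow in the drug (R8, RA2, R9 and R2, 1 array each). Imatinib blocks the receptor tyrosine kinase KIT, on which this tumour type usually depends. Selection began at 10 nM, and the resistant lines were later kept in 1 µM and needed over 500 times the parent's dose for the same inhibition. The comparisons ask what resistant lines have in common, how cells in short exposure differ from both, and how far the separately selected lines differ from each other. Values are log2 ratios unless stated, and the resistant group alone has replicates. Across genes, which are not independent replicates, R8 was the array most like T1 (correlation 0.962), and T117 had a correlation of 0.937 with T1. The pair least alike was RA2 and T117 (0.914).

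KIT was well above background on all 6 arrays. On its brightest probe KIT was 4.04-fold above T1 in R9 and 1.86-fold above in T117, while it was 1.7-fold below in RA2 and 1.51-fold below in R2. In R8 that probe's ratio was -0.07 and turned sign with quantile normalization and with median centring, while the other KIT probes gave -0.79 and -0.54. The 3 probes gave 2.02, 1.26 and 0.06 in R9, 0.90, 1.40 and 1.29 in T117, -0.76, -1.54 and -1.24 in RA2 and -0.60, -1.63 and -0.59 in R2, so the size of each difference depends on the probe. PDGFRA, a related receptor kinase, was 1.86-fold above T1 in R8, 1.6-fold in R9 and 1.47-fold in R2, and 1.3-fold below T1 in T117. No KIT or PDGFRA difference between the resistant group and a lone array passed the limma threshold.

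T117 against T1 asks what 7 weeks of imatinib did to the parental cells. Genes of cell division were far below the parent. All 31 measured genes of the cell cycle list were at least 2-fold lower in T117, with a median of -3.47, below each of 10000 random lists. These genes varied together (estimated correlation 0.71), unlike those of random lists. PLK1, a mitotic kinase, was 37-fold lower, CCNA2, a cyclin of S and M phase, 25.4-fold, TOP2A, a DNA topoisomerase, 22.5-fold, and MCM2, of the replicative helicase, 4.39-fold. In the DNA repair list 12 of 25 genes were at least 2-fold lower, among them FANCI (-2.77) and BRCA1 (-2.11). MYCN, a growth-promoting transcription factor, had the lowest ratio of the genes measured above background in both arrays, 135-fold below T1.

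Transcripts that report MAPK signalling, a pathway downstream of KIT, were lower in T117. In the MAPK output list 8 of 17 genes were at least 2-fold lower and 2 higher, with a median of -0.93. The phosphatase DUSP6 was 21.9-fold lower, the feedback inhibitor SPRY2 13.7-fold and the transcription factor ETV5 12.6-fold, and ETV4 was at least 15.4-fold lower. The 2 higher members were EPHA4 (2.24) and MYC, at least 62.2-fold above the limit of detection in T1. Genes of cholesterol synthesis had a median of -0.85 (9 of 24 at least 2-fold lower, 1 higher), with DHCR7 at -1.96. Hypoxia and glycolysis genes had a median of -0.60, with hexokinase HK2 at -3.12 and phosphofructokinase PFKP at -2.57. Heat shock genes had a median of -0.71.

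Smooth muscle genes were the list furthest above the parent in T117, with a median of 1.21 and 7 of 15 members at least 2-fold higher. The enteric smooth muscle actin ACTG2 was 12.1-fold higher, the myosin light chain kinase MYLK 6.73-fold, and MYH11, smooth muscle myosin, at least 12.6-fold. The list of the tumour lineage had a median of 0.52 with 5 members at least 2-fold higher, among them ETV1 (3.91-fold, and higher on all 4 of its probes), HAND1 (1.81) and PRKCQ (1.75), and 2 lower, CD34 (-2.53) and BARX1 (-1.32). Interferon response genes had a median of 0.68, with 6 members at least 2-fold higher and 4 lower. IFIT2 (2.43) and SAMD9L (2.98) were higher, while USP18 had an upper bound of -3.25.

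The 10 highest ratios in T117 included FBXO32, a ubiquitin ligase of muscle atrophy (68.7-fold), RRAD, a small GTPase (79.8-fold), the bicarbonate transporter SLC4A4 (52.7-fold), REEP1 (36.7-fold), TNFSF4 (35.5-fold) and the potassium channel KCNK3 (34-fold). SECTM1, LHPP, RCAN2 and HSPB7 were between 28.3 and 32.8-fold higher. Besides MYCN and PLK1, the 10 lowest were KLHDC8A (116-fold), TBX2 (56-fold), the histone H3C15 (41.1-fold), the growth factor binding protein IGFBP2 (38.1-fold), CDCA7, IGDCC3, DLGAP5 and SLC45A3 (28.5-fold). Genes detected in T117 but not in T1 were led, after MYC, by SCEL, SNTG2, FAM83E and NOX1, at least 33.4-fold higher. Genes lost from detection in T117 were led by TMEM233 (at least 95.5-fold), PKP1 (at least 46-fold), HAO1, LEFTY1 and KCNN4 (at least 30.9-fold). In all, 1651 genes were at least 2-fold higher and 1862 at least 2-fold lower in T117, with no test, since each side is 1 array.

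**Figure D1:**
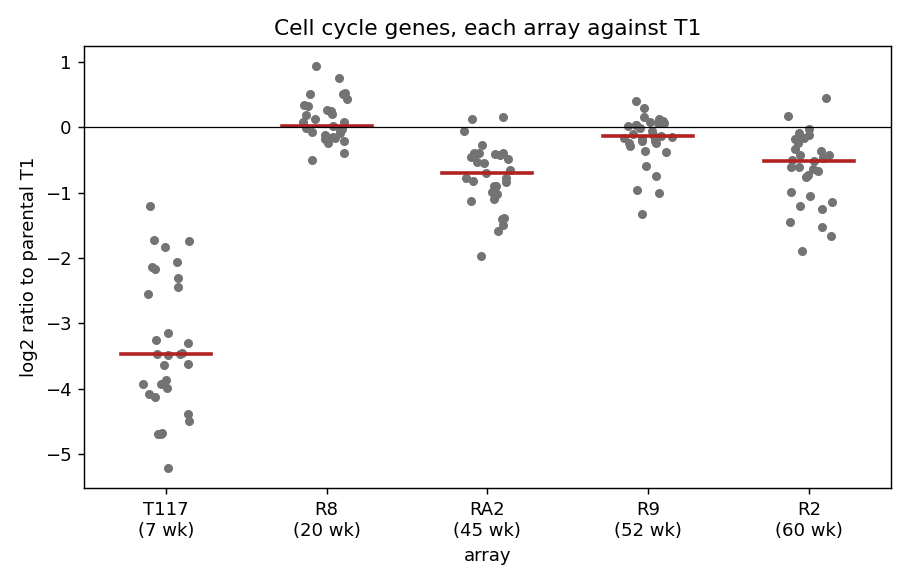
Log2 ratio to T1 (vertical axis) of the 31 genes of the cell cycle list in each array (horizontal axis), 1 point per gene, with CDC6 in T117 drawn at its bound and the median as a red bar. T117 has a median of -3.47, while the medians of the 4 resistant lines lie between -0.70 and 0.01.

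The resistant lines against T1 ask what resistance has in common over 4 separate selections. By camera's preset correlation, genes of the unfolded protein response were lower as a group and genes regulated by FOXO factors and by p53 were higher. None of these calls held with an estimated correlation (adjusted p = 0.929 for each). The p53 list lost its call there too, although its estimated correlation of 0.0016 was below the preset 0.01. That setting rests on the 3 residual degrees of freedom, so a call lost there need not reflect correlation between genes. The estimated correlation was above the preset for the unfolded protein response (0.084) and FOXO targets (0.086). It was also above it for cholesterol synthesis (0.24), interferon response (0.49) and cell cycle (0.71). For these lists the preset may give p-values that are too small. T117 lay on the same side of T1 for the unfolded protein response (median -0.41) and FOXO targets (0.36), and the resistant lines differed from it by means of -0.13 (adjusted p = 0.721) and 0.06 (0.994, where the median was -0.17 and the test pointed down), so neither shift was shown to be particular to resistance. Counts of genes on the same side of T1 in all 4 lines are given here and below without an expected number. The 4 ratios share T1, so they fall on the same side more often than independent ratios would. In the unfolded protein response list, 15 of 19 genes were lower than T1 in all 4 lines and 1 was higher, with a mean difference of -0.59. HSPA5, the main chaperone of the endoplasmic reticulum, ran from -0.55 in R2 to -1.32 in R8, and DNAJC3 from -1.99 in RA2 to -1.02 in R8. Of 24 cholesterol synthesis genes 11 were lower in all 4 lines and 2 higher (mean -0.39), with DHCR7 between -2.01 and -0.69. Of 15 FOXO targets 6 were higher in all 4 lines and 0 lower (mean 0.65), led by the insulin receptor INSR, which lay between 2.93-fold in R8 and 8.53-fold in RA2.

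Of 20 p53 targets 11 were higher in all 4 lines and 1 lower (mean 0.47). T117 did not share this shift (median -0.00), and the resistant lines exceeded it by a mean of 0.63. That difference did not pass camera with the preset correlation (adjusted p = 0.0538) or an estimated one (0.756). The p53 shift was therefore not shown to be particular to resistance either. TP53INP1 lay between 1.14 and 2.04, while GDF15, a stress cytokine, was 3.71 in RA2 and 3.26 in R2 but -1.19 in R8. Of 28 interferon response genes 9 were higher in all 4 lines and 2 lower (mean 0.47). The list's median was 1.04 in R9, 0.92 in R2, 0.23 in R8 and -0.07 in RA2, the last turning sign with the series table. IFIH1, a sensor of viral RNA, was at least 1.30 in R8 and at least 3.60 in R2. In the cell cycle list, 10 of 31 genes were lower in all 4 lines and 2 higher (mean -0.37), with medians from -0.70 in RA2 to 0.01 in R8. T117 lay on the same side of T1 for interferon (median 0.68, resistant against T117 mean 0.17, adjusted p = 0.966), cholesterol synthesis (-0.85) and cell cycle (-3.47), so none of these 3 shifts was shown to be particular to resistance.

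With camera's preset correlation these 6 of 35 lists passed: unfolded protein response (adjusted p = 0.000721), FOXO targets (0.038), p53 targets, interferon response and cholesterol synthesis (0.0383 each) and cell cycle (0.0487). None passed with an estimated correlation (adjusted p = 0.929 for each of the 6) or with fry, where the unfolded protein response had an adjusted p of 0.514, p53 targets 0.606 and the other 4 lists 0.989. With little power, the setting with an estimated correlation cannot decide whether a list is shifted. The calls for the unfolded protein response and FOXO targets held without any single line, up to adjusted p values of 0.0066 and 0.0451. Scaling or background ended every call but that of the unfolded protein response under some setting. The series table ended FOXO (0.0528), p53 (0.0528), interferon, cholesterol and cell cycle (0.0623 each), and quantile normalization cell cycle (0.233) and cholesterol (0.191). With the series table the means of FOXO, p53 and interferon were larger (0.757, 0.572 and 0.575, against 0.65, 0.47 and 0.47). Those of cholesterol (-0.289) and cell cycle (-0.269) were smaller, as they were with quantile normalization (-0.283 and -0.254). Median centring ended cell cycle (0.0733), p53 and cholesterol (0.0648 each), normexp p53 (0.0706), and the mean over probes p53 and interferon (0.063 each). With median centring the means hardly moved (-0.369, 0.472 and -0.389). Normexp gave p53 a mean of 0.337, and the mean over probes gave p53 0.422 and interferon 0.451. The p53 call was lost without R9 (0.0818), the interferon call without R9 (0.121) or R2 (0.24), the cholesterol call without R8 (0.0539) or R9 (0.172), and the cell cycle call without RA2 (0.343), R9 (0.0818) or R2 (0.17). The mean was 0.50 for p53 without R9, 0.30 and 0.22 for interferon without R9 and R2, -0.39 and -0.30 for cholesterol without R8 and R9, and -0.25, -0.43 and -0.28 for cell cycle without RA2, R9 and R2. With T1 and T117 as one group the FOXO and interferon calls were lost too (0.229 each), and the cell cycle list turned to a mean of 1.29, since T117 is low in it.

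No single gene passed limma in the resistant lines against T1. The lowest adjusted p was 0.105, and 909 genes had an unadjusted p under 0.05 (350 higher and 559 lower), where chance gives 854. With quantile normalization 77 genes passed (2 higher, 75 lower) and with median centring 25 (2 higher, 23 lower). Adjusted over the list alone, 2 genes of the WNT list passed and no gene of another list, against 0 over all genes. DLX2, a homeobox factor, was 27.7-fold lower on average (mean difference -4.79, standard error 0.58, n = 4, limma adjusted p = 0.131) and between 18.5-fold and 47.2-fold lower in each line. DKK3, a secreted WNT modulator, was 11.2-fold lower on average, with -4.20 in R2 and -2.64 in R9. TMEM252 (-3.80), NPR3 (-3.75), CIMAP1A (-3.44), MOBP (-3.26) and PRSS35 (-3.13) were among the next lowest means. TP73 (-3.55) and ART5 (-2.87) were in the same range, but another probe of each went the other way. In T117, DLX2 (-4.22), DKK3 (-2.25), TMEM252 (-3.15), CIMAP1A (-3.07), PRSS35 (-2.13), TP73 (-3.62) and ART5 (-3.54) were lower than T1 as well, while NPR3 (0.77) and MOBP (-0.17) were near it or above. TMEM252, MOBP and PRSS35 were each undetected in 1 resistant line, whose dim signal entered the mean. PKP1, QPCT, GJB1, CD160 and F9 were detected in T1 alone, so their resistant mean was at least 56.6-fold lower for PKP1 and at least 26.3-fold for F9.

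Among genes detected in T1 and at least 2-fold higher in all 4 resistant lines, CELF4, an RNA-binding protein, had the highest mean (3.51, standard error 1.36, n = 4, limma adjusted p = 0.918). APCDD1, a WNT inhibitor and target, followed at 3.07, then ARHGEF26 (3.04), KCNMB4 (2.97), CNTNAP2 (2.93), REEP1 (2.84), the glutathione transferase GSTA4 (2.79), DEPP1 (2.79), HEY1, a NOTCH target (2.77), and FBXO2 (2.77). APCDD1, REEP1, GSTA4, DEPP1 and FBXO2 were higher in T117 too, by 1.03 to 5.20. MAL2, a membrane trafficking protein, was not detected in T1 or T117 and was at least 19.9-fold above T1 on average, followed by GCA, COLEC10 and ANXA10 (at least 10.6-fold). MATN4 had a mean of at least 10.9-fold but was undetected in R8. None of these passed the threshold. Slide and group coincide here, so a difference between slides cannot be told apart from one between groups.

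The resistant lines against T117 ask what separates cells that grow in imatinib from cells in short exposure. All 31 cell cycle genes were higher in each of the 4 resistant lines than in T117, with a mean difference of 2.95. The 4 ratios share T117, so counts over all 4 lines exceed those of independent ratios, and no expected number was computed. DNA repair genes (mean 0.98) were higher in all 4 lines for 15 of 25 members and lower for 2. In the MAPK output list (mean 1.16) 10 of 17 were higher in all 4 lines and 3 lower, with DUSP6 28.7-fold higher on average, and in hypoxia and glycolysis (mean 0.68) 12 of 25 were higher and 0 lower.

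With camera's preset correlation these 4 lists passed, all higher: cell cycle (adjusted p = 4.12e-31), DNA repair (5.05e-06), MAPK output (0.00221) and hypoxia and glycolysis (0.0144). With an estimated correlation none did (adjusted p = 0.756 for cell cycle and for DNA repair, 0.837 for MAPK output and 0.864 for hypoxia and glycolysis), nor with fry (0.0872, 0.0872, 0.207 and 0.495). The estimated correlations were 0.71 for cell cycle, 0.057 for DNA repair, 0.13 for MAPK output and 0.17 for hypoxia and glycolysis. All lie above the preset 0.01, so the preset may give p-values that are too small. With the preset correlation each of the 4 calls held without any single resistant line. This contrast by camera was added after the data were seen.

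No gene passed limma in this contrast either, with a lowest adjusted p of 0.0776. There were 200 genes with an adjusted p under 0.1, and 2040 with an unadjusted p under 0.05 (1164 higher and 876 lower). Between 32 and 213 genes passed with normexp, quantile normalization, a filter on all 6 arrays, or limma's trend and robust settings. Adjusted over the list alone, 29 of 31 cell cycle genes, 9 DNA repair genes, 5 MAPK output genes and at most 4 genes of any other list passed, against 0 over all genes. MYCN had the highest mean difference (6.46, standard error 0.78, n = 4, limma adjusted p = 0.0776), followed by KLHDC8A (5.88), H3C15 (5.46), SERPINF1 (5.21) and TOP2A (4.90). DUSP6, CYP2J2, SLC45A3, CORO2A and IGF2BP3 lay between 4.63 and 4.84. The highest bounds belonged to TMEM233, COL15A1, CCKBR, ST6GAL1 and the mitotic kinase NEK2, at least 23.5-fold to at least 55.5-fold. The lowest means were those of FGL2 (-6.08), RRAD (-5.25), the cyclin-dependent kinase inhibitor CDKN1C (-4.86), NPR3 and KCNK3 (-4.53 each), with MAGEH1, FAM83E, LRRC3B, TNFSF4 and SULF1 up to -4.12. FGL2, RRAD, FAM83E, LRRC3B and TNFSF4 were undetected in R9, whose dim signal entered the mean. PCDH9, NOX1, DEFB107A, KRTAP21-3 and POU4F2 were detected in T117 alone, and their resistant mean was at least 16-fold to at least 34.5-fold lower.

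Genes that set all 4 resistant lines apart from both T1 and T117 were counted without a test. There were 112 of them at least 2-fold the same way in all 8 ratios, 49 higher and 63 lower. By the smallest of the 8 ratios, MAL2 led those higher (at least 7.59-fold, since T1 and T117 had no detected signal), followed by HEY1 (4.03-fold), FAM177B (3.96-fold), COLEC10, the small heat shock protein HSPB8, SNX7, KATNAL2, CELF4, the WNT target SP5 and GCA (at least 2.81-fold). FMO4, a monooxygenase, led those lower (at least 4.38-fold), followed by NPR3, the natriuretic peptide clearance receptor (3.59-fold), the drug-metabolising enzyme CYP3A4 (at least 3.44-fold), with RTN4RL1, OR5L2, NKG7, the transcription factor MAF, RNF222 and KRTAP19-8 (2.86-fold) among the next.

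In 20 simulated sets of unchanged arrays the mean number of such genes was 30.5 and the highest 41. With every other pair of the 6 arrays in the place of T1 and T117, RA2 and R2 gave 170 such genes, and the remaining pairs 11 to 105, so 2 of 15 pairs, the real one included, reached 112. The count was 252 without R9 and 203 without R8, and 46 with normexp background correction, 43 of them shared. Against T1 alone, 152 genes were at least 2-fold higher and 291 lower in all 4 lines. The simulated means were 123 and 164, where independent ratios with the observed counts per line and all genes alike would give 1.04 and 1.11. The simulated ratios share T1 and each gene has its own spread, and the part of each in that gap was not separated. Against T117 alone the counts were 811 and 466 (simulated 114 and 167, independent 5.21 and 3.16).

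Each resistant line against T1 asks what that line carries, with 1 array on each side and no test. R8, selected for 20 weeks, was closest to the parent, with 791 genes at least 2-fold higher and 1240 lower. With median centring 64.6% of its genes at least 2-fold apart were higher, against 38.9% here, so its balance of higher and lower genes depends on the scaling. The integrated stress response (median -0.40, 7 of 26 at least 2-fold lower) and matrix genes (-0.49) were lower in R8. POSTN, a matrix protein, was -3.82 and the early response gene EGR1 -4.69.

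RA2, selected for 45 weeks, had 2138 genes higher and 1845 lower. Its integrated stress response list had a median of 1.22, above each of 10000 random lists, with 18 of 26 genes at least 2-fold higher and 0 lower. ASNS, asparagine synthetase, was 7.86-fold above T1, CHAC1 10-fold, CTH 7.75-fold, DDIT3, a stress transcription factor, 6.27-fold and PHGDH, of serine synthesis, 4.04-fold. Ribosomal protein genes had a median of 0.82, also above each random list, with 13 of 36 at least 2-fold higher. Genes of the stress response list and of the ribosomal list varied together (estimated correlations 0.67 and 0.84), unlike those of random lists. Such a position is therefore reached more easily. MYC was at least 151-fold above T1 in RA2. MAPK output genes had a median of 0.74, with 7 of 17 at least 2-fold higher, and YAP targets 0.62.

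R9, selected for 52 weeks, had 1536 genes higher and 1187 lower, and with median centring 36.3% of them were higher, against 56.4% here. Interferon response genes had a median of 1.04, with 14 of 28 at least 2-fold higher, and genes of MHC class I antigen presentation 0.85, with 5 of 16 higher. PSMB8, of the immunoproteasome, was 5.8-fold above T1 and IFIH1 at least 11.2-fold. Hypoxia and glycolysis genes had a median of 0.52 and NRF2 targets 0.62, with HMOX1 at 1.85. Matrix genes had a median of -1.08, with 15 of 31 at least 2-fold lower, among them TGFBI (-4.59) and COL5A2 (-3.32). TGF-beta and BMP targets had a median of -0.60.

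R2, selected for 60 weeks, had 1991 genes higher and 2027 lower, and 67% of them were higher with the authors' series table, against 49.6% here. It differed from R9 in matrix genes, with a median of 0.57 and 11 of 31 at least 2-fold higher, and in YAP targets (0.90) and TGF-beta and BMP targets (0.83). BGN, the proteoglycan biglycan, was 3.43 in R2 and 3.42 in R9, while SPARC was 1.70 in R2 and -1.17 in R9. Interferon response genes had a median of 0.92, with 12 of 28 at least 2-fold higher, while those of MHC class I had -0.50. Smooth muscle genes had a median of 0.62, with ACTG2 at 3.23. Differences between lines in these medians were not tested.

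**Figure D2:**
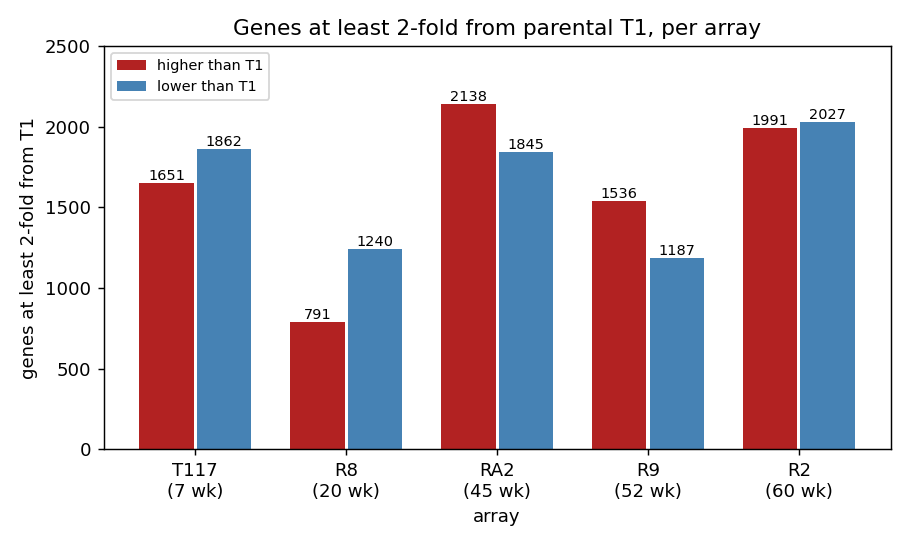
Number of genes at least 2-fold higher (red) or lower (blue) than T1 (vertical axis) in each array (horizontal axis, with weeks in imatinib). R8 has the fewest in total, 791 higher and 1240 lower, while R9 has the fewest lower, 1187.

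**Figure D3:**
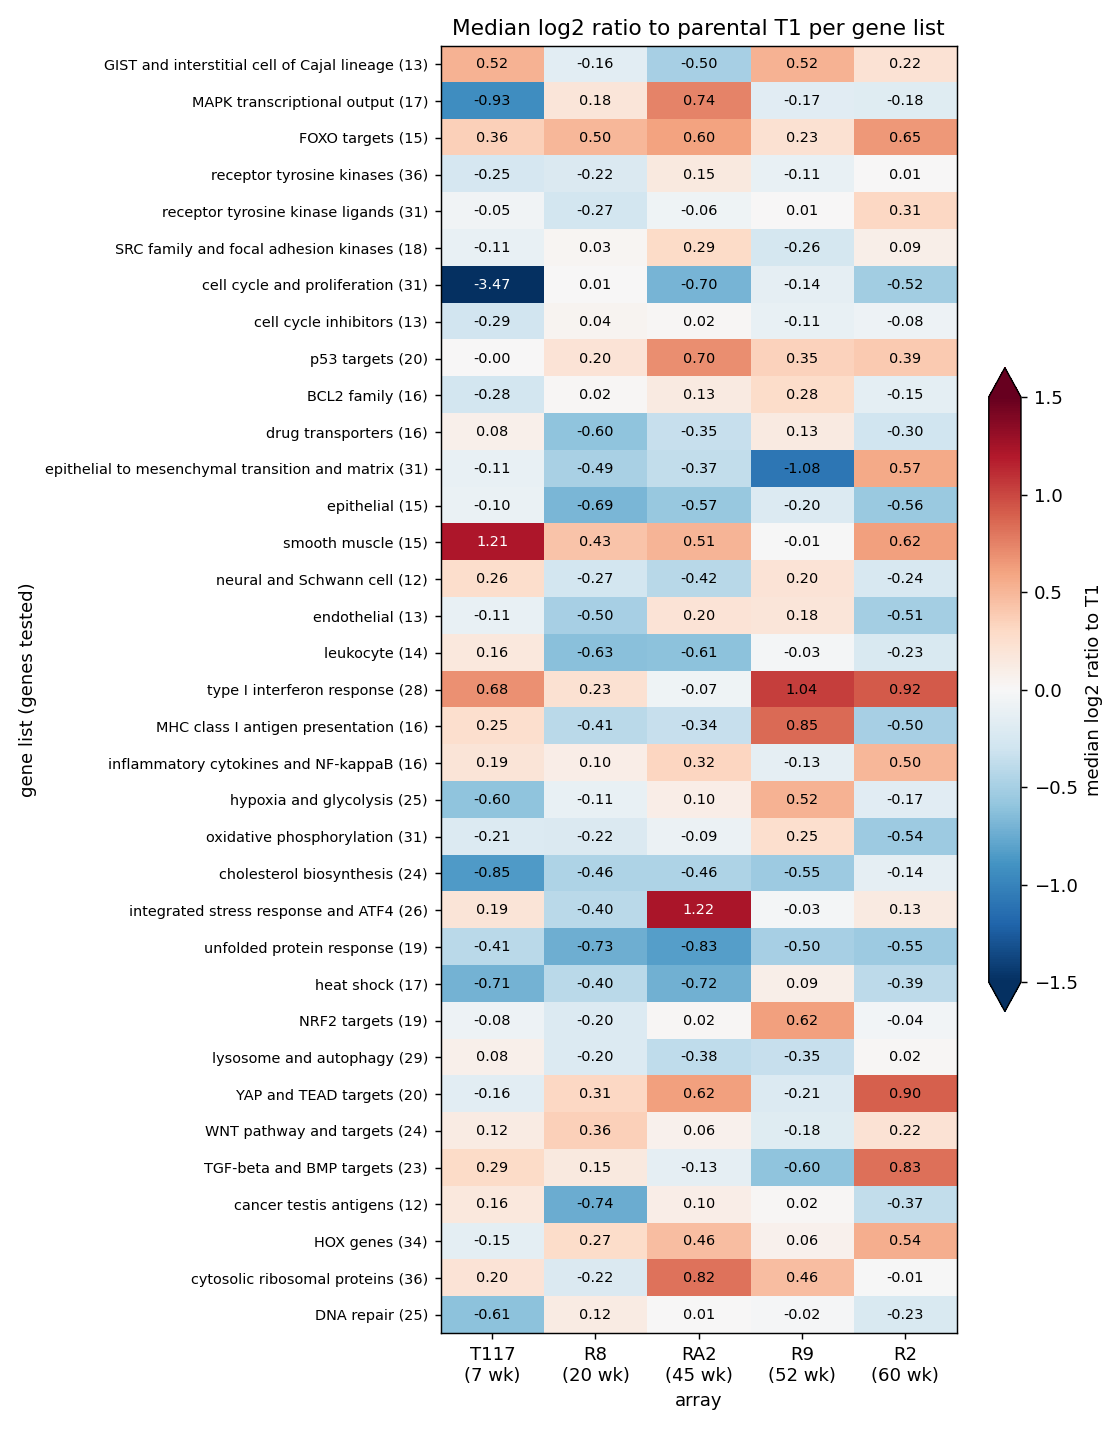
Median log2 ratio to T1 of each of the 35 gene lists (vertical axis, with the number of genes tested) in each array (horizontal axis), printed in each cell, with colours that stop at 1.5 either way. The lowest value is the cell cycle list in T117 (-3.47) and the highest the integrated stress response in RA2 (1.22).

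The resistant lines also differed from each other. In all, 566 genes were at least 4-fold above or below each of the other 3 lines, 43 in R8, 124 in RA2, 202 in R9 and 197 in R2. This count was not set against simulated arrays. The lines correlated with each other at 0.926 to 0.953 and with T1 at 0.930 to 0.962. R2 stood out for ASS1, argininosuccinate synthetase, at least 89.3-fold above each other line and 1160-fold above T1, with RGS18, A2M, RASAL3 and KCNK2 behind it. DSP, a desmosome protein, was at least 74.4-fold below each other line in R2, with ENTPD3, ARHGAP44, NPFFR2 and ZSCAN18 behind it, although another probe of ZSCAN18 went the other way. R9 stood out for a loss of COL4A2, a basement membrane collagen (70.8-fold below each other line), the RNA-binding protein IGF2BP2 (58.2-fold), the inflammatory caspase CASP4 (at least 37.8-fold), the G1 cyclin CCND1 (at least 33.9-fold) and PTPRK (at least 31.1-fold), the last 3 undetected in R9. TMEM71 was at least 164-fold above each other line in R9, followed by PLA2G2F, THPO, IGFBP5 and DNAH6.

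RA2 stood out for MYC, at least 49.7-fold above each other resistant line, and for CLEC1A, SP6, ANXA1 and MAGEA2B, each at least 15.9-fold. The lowest in RA2 were SLC4A4 (7.73-fold), CLDN20, CLEC18B, NPTX1 and VSTM2A. R8 stood out for SPOCK1 (at least 39.1-fold), the survival kinase PIM1 (29.4-fold), LDOC1 (at least 25.3-fold), BCL2L14 and KCNC1. The lowest in R8 were MATN4 (at least 20.9-fold), TSPO (10-fold), TSKS, LEMD1 and MIEF1, of which MIEF1 had 2 other probes going the other way. With normexp background correction the total was 177, and with a filter on all 6 arrays 216.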

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

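The contrast of the resistant lines with T117 by camera, the count over other pairs of reference arrays, the comparison of spike-in slopes and the test on lineage genes were chosen after the result was seen. The gene lists and the rule for naming genes were fixed before the data were examined.

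In 4 lists the resistant lines differed from T117 by camera's preset correlation, although T117 is 1 array and lies on the other slide. They were cell cycle (adjusted p = 4.12e-31, mean difference 2.95, higher in 4 of 4 lines for all 31 genes), DNA repair (adjusted p = 5.05e-06, mean 0.98), MAPK output (adjusted p = 0.00221, mean 1.16) and hypoxia and glycolysis (adjusted p = 0.0144, mean 0.68). With an estimated correlation the adjusted p values were 0.756, 0.756, 0.837 and 0.864, and with fry 0.0872, 0.0872, 0.207 and 0.495. The estimated correlations, 0.71, 0.057, 0.13 and 0.17, were above the preset 0.01, so the preset p-values may be too small. The setting with an estimated correlation rests on 3 residual degrees of freedom and had little power.

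For the low cell cycle genes of T117, the scaling of that array is argued against, since the list's median stayed at -3.21 or lower under each of the 4 other scalings and background corrections. RNA from non-dividing cells that lack tumour lineage genes is argued against as well. Those genes were not diluted in T117 (median 0.52, with 5 members at least 2-fold higher and 2 lower). Smooth muscle genes, counted among markers of other cells, were higher in T117 (median 1.21). The lineage list cannot exclude non-dividing cells that share its genes. A second list of 40 cell cycle genes, none of them in the first, had a median of -3.34 in T117, with 38 at least 2-fold lower, but this restates the pattern in more genes. Fewer dividing cells can therefore not be told apart from another cause of low cell cycle transcripts, and imatinib and the state of the culture at harvest stay open, since T117 is 1 array.

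For the 112 genes that set the resistant lines apart from both T1 and T117, a trend with signal is argued against for the 88.4% that kept all 8 ratios after quantile normalization. Fewer of the 112 were kept with median centring (81) and with normexp (43), whose offset shrinks ratios. Independent noise alone gave at most 41 such genes in 20 simulated sets, but a limit from that simulation excludes too much, because real arrays differ by more than independent noise. The pair RA2 and R2 as references gave 170 genes and the remaining pairs 11 to 105, and 15 pairs are too few for a share under 0.05, so chance differences between lines cannot be told apart from resistance. Another difference between the slides cannot be told apart either, since slide and group coincide and the lowest spike-in slope on slide 1 exceeded the highest on slide 2 by 0.037. A shared programme of resistance stays open as a hypothesis.

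Of 12163 probes without a gene name, which no comparison used, 76 were at least 2-fold the same way in all 8 ratios, 8 higher and 68 lower, against 49 and 63 of the named genes. This count was not set against simulated arrays.

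Among 110 tested values of the resistant lines (75 genes and 35 list medians), 6 had 1 line far from the other 3, where chance gives 5.5. The measure is the gap to the nearest line as a share of the group's range, against Dixon's critical value for 4 samples. MHC class I genes had a median of 0.85 in R9 against -0.50 to -0.34 in the others (share 0.887). TP73 was -3.21 in R9 against -3.70 to -3.64 (0.893). H3C15 was 0.98 in RA2 against -0.27 to -0.11 (0.872). KCNK3 was 1.54 in R2 against 0.12 to 0.33 (0.85). SNX7 was 2.65 in R2 against 1.76 to 1.90 (0.834), and MAF -2.13 in R2 against -1.64 to -1.56 (0.859).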

How the results depend on the processing

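The normexp correction on median pixel intensity and the contrast with T117 by camera were chosen after the data were seen. Of the counts, 85 stayed within 1.5 times under an alternative and 32 did not. Of the list tests, 912 stayed on the same side of the threshold, 43 lost their call, 23 gained one and 2 reversed. The 912 include lists passing in neither setting, whose direction was not compared. The losses and reversals all lie in the 6 lists passing against T1 and the 4 against T117. Each of the 6 had 15 alternatives and each of the 4 had 13. Of the values of named genes 1390 stayed within 1 standard deviation and 89 did not, and of the list medians 1115 and 110. The cause was not tested unless stated.

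Genes passing limma against T1 numbered 77 with quantile normalization (2 higher, 75 lower) and 25 with median centring (2 higher, 23 lower), with 0 under the other settings. Against T117 they numbered 176 with normexp, 32 with quantile normalization, 213 with the filter on all 6 arrays, where fewer genes are tested, and 169 with trend and robust settings. The 8-ratio genes numbered 46 with normexp, 3 at 4-fold, and 151 to 252 without 1 line, where fewer ratios must pass. Genes at least 2-fold from T1 numbered 889 in R8, 2542 in RA2, 1613 in R9 and 2480 in R2 with normexp, whose offset shrinks ratios, and 1131 in R8 with the filter on all 6 arrays. At 4-fold they numbered 1075 in T117, 377 in R8, 923 in RA2, 562 in R9 and 952 in R2. Set-apart genes numbered 177 with normexp, 216 with that filter and 2806 at 2-fold.

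Lists passing against T1 numbered 3 with median centring, 1 with the series table, 0 with an estimated correlation, 0 with fry, and 2 to 6 without 1 line. With T1 and T117 as one group, cell cycle reversed to 1.29 (adjusted p = 1.79e-06, range over alternatives 1.79e-06 to 0.989) and cholesterol to 0.039 (adjusted p = 0.915, range 0.00518 to 0.989), since T117 is low in both. The adjusted p ranged from 3.53e-06 to 0.929 for the unfolded protein response, 0.0076 to 0.989 for FOXO targets, 0.0081 to 0.929 for p53 targets and 0.000587 to 0.989 for interferon.

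Calls were also gained against T1 by ribosomal proteins (quantile normalization, without R8 or R2) and matrix genes (without R2), and against T117 by HOX, p53 and cholesterol genes under at least 3 settings each and by neural, leukocyte, MHC class I, YAP and WNT genes without R9. The median log2 ratio of all genes moved by 0.10 or more with median centring in R8 (0.23) and R9 (-0.23), with quantile normalization in R8 (0.12) and R2 (0.10), with the series table in T117 (0.12), R8 (0.11) and R2 (0.20), with normexp in R9 (0.10) and with no filter in R8 (-0.10) and R9 (0.11). Of 175 list medians 47 turned sign under a scaling or background correction, none beyond 0.43 either way. The filter on dim probes could not change the fold counts, which need signal above background. A block for the slide could not be fitted. Between 52.4% and 60.5% of probes were well above background, so single ratios of dim genes are bounds. The limma fits, list tests and list medians used the dim signal itself.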

Other observations

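The tests on gene order, on R9's run alone and without the nearest array were chosen after the result was seen. Single receptor kinases other than KIT differed from T1 in the resistant lines, although their list had medians between -0.22 and 0.15 in the 4 lines, those of R8 and R2 turning sign with median centring. The insulin receptor INSR was higher in every array, with 2.40 in T117 and 3.09 in RA2. IGF1R, undetected in T1 and T117, was at least 1.20 in R8 and at least 3.50 in RA2. ERBB3 was 2.54 in RA2 and 1.97 in R2 but -0.61 in R9, and FLT1, a receptor for vascular growth factors, -3.08 in R9. Among their ligands (medians -0.27 to 0.31), NRG2, a ligand of ERBB receptors, was 3.90 in T117 and between 1.22 and 2.21 in the resistant lines. KITLG, the ligand of KIT, was -2.21 in T117 and 2.02 in R2, and PDGFC was detected in R2 alone, at least 4.80. SRC family and focal adhesion kinases had medians between -0.26 in R9 and 0.29 in RA2.

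Regulators of cell death and division varied by gene. BMF, a promoter of apoptosis, was higher in all 5 arrays than in T1, from 1.48 in R9 to 3.46 in T117, and BID, another, was -2.79 in T117. The BCL2 family had medians between -0.28 in T117 and 0.28 in R9. CDKN1C, a brake on division, was 1.69 in T117 but -4.47 in RA2, -3.01 in R9 and -4.88 in R2, while the inhibitor list as a whole had medians between -0.29 and 0.04. Among drug transporters (medians -0.60 in R8 to 0.13 in R9, the latter turning sign with quantile normalization and median centring) SLCO4A1 lay between -1.72 and -1.16 in the resistant lines.

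Developmental genes differed between lines. In the WNT list (medians -0.18 to 0.36) SP5, a direct target, was at least 1.84 to at least 4.59 in the resistant lines and undetected in T1 and T117. LEF1 (-3.33) and WNT5A (-3.76) were lower in T117, and RNF43 was 3.55 in R8 but -3.08 in R2. HOX genes had medians from -0.15 in T117 to 0.54 in R2, with HOXB6 at or below -3.58 in R9 and HOXD13 at -2.80 in T117. Oxidative phosphorylation had medians from -0.54 in R2 to 0.25 in R9, lysosome and autophagy from -0.38 in RA2 to 0.08 in T117, and inflammatory genes from -0.13 in R9, which turned sign with normexp, to 0.50 in R2. Markers of other cells had medians from -0.69 to -0.10 for epithelial, -0.42 to 0.26 for neural, -0.51 to 0.20 for endothelial and -0.63 to 0.16 for leukocyte genes, and cancer testis antigens -0.74 to 0.16. None of the lists in these 3 paragraphs passed camera against T1 in the main setting. With a filter on all 6 arrays drug transporters (mean -0.63) and epithelial genes (-0.52) passed, each with an adjusted p of 0.0295, the lowest over their alternatives. With T1 and T117 as one group HOX genes passed (mean 0.42, adjusted p = 0.0499) and so did DNA repair (mean 0.48, adjusted p = 0.0151), again the lowest over their alternatives. These calls used camera's preset correlation. In the main setting camera with an estimated correlation gave each of these 4 lists an adjusted p of 0.929. Fry gave each an adjusted p of 0.989, the highest over their alternatives. For endothelial genes the mean over the resistant lines was 0.15 while the median was -0.39 and camera's direction down. Mean and test also differed in sign for cell cycle inhibitors (mean -0.18) and DNA repair (mean -0.02), both up by the test, as did median and mean for receptor kinases (-0.02 and 0.11), their ligands (-0.02 and 0.12) and WNT (-0.07 and 0.13).

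Neighbouring genes shifted together, in runs of 50 genes in genome order, in all 5 arrays set against T1. The run furthest from 0 was that from TIMP2 to LRRC45 in RA2 (median -1.22, and -0.94 in R2) and CEP131 to FN3KRP in R2 (-1.10, and -1.08 in RA2). In R9 it was BMP1 to GSR (-1.08), with smaller ones from NR2C2AP to RHPN2 in T117 (-0.75) and NICOL1 to TAPT1 in R8 (0.54). Chance order is argued against, since 0 of 1000 shuffles gave a run as large in RA2, R9 or R2. A trend shared by all arrays is argued against for R9's run from BMP1 to GSR, where 82.7% of the shift was left after prediction from the other arrays. Base composition was not measured, and an effect of it on R9's array alone would leave the same share, so it stays open. In R2 23% and in RA2 56% was left, but 67.7% and 81.8% when these lines were not used to predict each other. R9 was at 0.04 in R2's run, so a trend of RA2 and R2 cannot be told apart from a regional change they share. R9's next lowest separate run, from GATD1 to HBG1 (-0.72), was low in RA2 (-0.69) and R2 (-0.83) too. It was at -0.26 in R8 and -0.02 in T117, and a shared trend was not tested for it. A change in copy number stays open too, since the runs were picked for their medians, so that at least 94% of genes on the shifted side in RA2, R9 and R2 does not favour it.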
